A study of Arabidopsis thaliana with 6 samples.

How the data were processed

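The samples were whole seeds of Arabidopsis thaliana, 3 libraries from the wild-type accession Col-0 and 3 from hda15-1, a mutant of the histone deacetylase gene HDA15. Per the labels' protocols, seeds took up water for 1 h, received far-red light for 5 min at 3.82 µmol per square metre per second and were held in darkness at 22 °C for 12 h before RNA was extracted. Messenger RNA libraries were made with an Illumina kit.

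The authors deposited 1 table of FPKM values per library (fragments per kilobase of transcript, scaled to mapped reads), per the file headers. The submitters' processing notes name Bowtie 0.12.2, Cufflinks, Cuffdiff and the genome build TAIR10, without saying which settings were used. The annotation version, the read length and whether counting used strand are not given in the sources used here. Each table held 32884 rows, of which 32538 matched a locus of the reference annotation and 61 carried only an assembly number. FPKM depends on the length assigned to each transcript, so levels of very short genes are uncertain. An exact 0 can be a failed estimate: 156 genes were listed at 0 in at least 1 library and above 5 FPKM in another, among them the storage protein gene CRC. For such genes the value of each library is given.

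Read totals are unknown. Comparing the lowest values of the same genes between libraries gave relative depths, with wild type 1 set to 1, of 1.25 for wild type 2, 1.21 for wild type 3, 1.18 for hda15-1 1, 1.03 for hda15-1 2 and 0.924 for hda15-1 3. Whole reads were not recovered from these steps, and no count test was run. At these depths a single read in a transcript of 1 kb was worth about 0.0890 to 0.116 FPKM, so values of that size rest on very few reads.

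Gene symbols, positions, exon lengths and GC content came from the TAIR10.1 reference annotation, joined by locus identifier. The tables hold no coordinates, and every position in the text is that of TAIR10.1.

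Differences were tested with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with the empirical Bayes trend, for the 15045 genes with a mean of at least 1 FPKM over the 6 libraries. Genotype was the only term. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over all genes tested, and the threshold was 0.05. A log2 fold change is hda15-1 minus wild type on the log2(FPKM + 1) scale, which understates the change of genes with low values. The labels do not say that the 3 libraries of a genotype came from separate seed lots, so p-values measure only the spread between these samples, which may be technical. In 3 libraries against 3, an exact permutation test of a single gene could not go below p = 0.1.

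The comparison, its test, 25 gene lists holding 331 loci and the rule for named genes were fixed before the data were examined. A list member was dropped where the annotation gave its locus another symbol, which removed 1 member, PIF8. Lists with at least 3 tested genes were tested with limma's camera at a preset correlation between genes of 0.01, with HDA15 left out, and p-values were adjusted over the 22 lists tested. Beside it stand camera with an estimated correlation and fry. The lists for gibberellin inactivation, with 1 tested gene, and for abscisic acid catabolism and the seed coat, with 2 each, were too small for the set test. After the main result was seen, 4 further lists were examined: indole glucosinolates, aliphatic glucosinolates, plasma membrane proton pumps and DNA damage response. They were chosen for genes already seen to differ, so no test of such a list as a whole is reported. The aliphatic list had 1 tested gene.

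The rule for named genes took HDA15 first. Of the genes past the threshold whose groups did not overlap, with a mean of at least 5 FPKM in the higher group, it took the 12 largest rises and up to 12 largest falls. From each list it took up to 4 tested members with the smallest p, and allowed any list member past the threshold. Genes named outside this rule are said to be so.

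The fit was tested on simulated values made with the levels and spread of the 15045 genes of this comparison, 200 of them changed. Of 50 genes changed 2-fold, 14 were recovered. Of 50 genes per size, 44 were recovered at 4-fold, 47 at 8-fold and 48 at 16-fold, all in the right direction, with 12 calls among the genes left alone. The simulated genes were drawn independently, with the spread as smoothed by limma, and without shifts shared within a library or failed estimates. Recovery in the real libraries may therefore be lower. Alternatives covered the pseudocount, the filter, the scaling between libraries, the variance model, a replicate block, each library left out and the set test. Others were added after the data were seen. These leave out the libraries numbered 1 or fit them as a batch, drop genes listed at 0 in some libraries, or remove trends on GC content and exon length, which were known for 98.6% of the genes tested.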

Results

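Transcript levels were measured by RNA sequencing in imbibed seeds held in darkness after a far-red pulse, a treatment that turns phytochrome to its inactive form and holds back germination. There were 3 wild-type libraries and 3 libraries of hda15-1. The series title names HDA15 with the basic helix-loop-helix factor PIF1 as a repressor of germination in the dark, and the question is which transcripts differ in seeds that lack HDA15. The FPKM values of a library summed to between 879239 in hda15-1 1 and 1159520 in hda15-1 3, and between 18902 and 19375 genes had a value above 0. Across genes, the log2 values of the libraries correlated at r = 0.937 to 0.980. This was 0.955 to 0.980 within wild type, 0.937 to 0.970 within hda15-1 and 0.945 to 0.973 between the genotypes. The lowest value was thus between libraries of hda15-1, below every pair of a wild-type and an hda15-1 library. Genes are not independent replicates. The 2 libraries that share the number 1 stood apart from the other 4 in some genes. Gene lists set them apart in camera only at the preset correlation, not with an estimated one. Differences are therefore also given among the 4 libraries numbered 2 and 3 alone.

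HDA15 (AT3G18520), on chromosome 3 from 6361159 to 6365705 on the plus strand, was the target gene and was low in every library labelled hda15-1. Its level was 14.6 ± 1.57 FPKM (SD, n = 3) in wild type and 0.469 ± 0.163 FPKM (SD, n = 3) in hda15-1. The log2 fold change was -3.41 ± 0.18 (SE), with an adjusted p of 3.79e-04 in limma. None of the other 12 histone deacetylase genes tested passed the threshold. HDT4, with the smallest p of them, was at 12.5 ± 0.825 FPKM (SD, n = 3) in wild type and 21.9 ± 8.43 FPKM (SD, n = 3) in hda15-1, with an adjusted p of 0.969 in limma.

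Most transcripts that differed were higher in hda15-1 seeds, with the expansin genes EXPA8 and EXPA1, the peptide gene GASA6, the protease gene CP1 and the glucosinolate gene CYP83B1 among the largest rises. Of 15045 genes tested, 30 were higher and 3 were lower in hda15-1 in limma, and all 33 differed by at least 2-fold. Their groups did not overlap, as held for 9.21% of all genes tested, where chance gives 10%. At an unadjusted p under 0.05, 464 genes were higher and 180 lower. Together these 644 were less than a share of 0.05 of the genes tested, which chance alone gives. Their number is thus no sign of differences beyond the 33. Among the 4 libraries numbered 2 and 3, with 14946 genes tested, 73 genes were higher and 12 lower, and 30 of the 33 were among them. These 4 are part of the libraries that gave the 33 and were chosen after the data were seen. The overlap is therefore not a replication. Leaving out 1 library moved the number of higher genes to between 8, without hda15-1 2, and 31, without wild type 1. It was 9 without wild type 2, 10 without wild type 3 and 10 without hda15-1 3. The number of lower genes was 5 without wild type 1. Of the 33, 9 passed whichever library was left out: HDA15, AT1G07887, AT2G05695, EXPA8, SOT16, AT5G45650, AT3G61820 and, named outside the rule, PME3 and CYP71B2.

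Among the 12 largest rises were 2 expansins and 3 protease genes. EXPA8 (AT2G40610), an expansin, a protein that loosens the cell wall, rose from 1.26 ± 1.31 to 35.6 ± 2.96 FPKM (SD, n = 3 each), a log2 fold change of 4.16 ± 0.35 (SE; adjusted p = 4.27e-03, limma). EXPA1 (AT1G69530) rose from 2.59 ± 1.26 to 57.2 ± 39.1 FPKM, a log2 fold change of 3.86 ± 0.46. GASA6 (AT1G74670), a small cysteine-rich peptide gene that responds to gibberellin, rose from 7.33 ± 6.48 to 129.3 ± 29.8 FPKM, a log2 fold change of 4.22 ± 0.48. CP1 (AT4G36880), a cysteine protease gene, rose from 2.01 ± 0.628 to 36.0 ± 16.6 FPKM. AT3G61820, of the aspartyl protease family, rose from 0.599 ± 0.277 to 9.26 ± 2.03 FPKM. AT5G45650, of the subtilase family, was listed at 0, 0.0840 and 0.0837 FPKM in wild type and at 5.35, 4.75 and 6.40 FPKM in hda15-1. OCT1 (AT1G73220), an organic cation transporter gene, rose from 1.296 ± 0.829 to 11.02 ± 1.37 FPKM. Adjusted p-values of these genes lay between 2.94e-03 for AT5G45650 and 0.0196 for EXPA1 in limma. EXPA1, GASA6 and OCT1 lost the call without wild type 2, with adjusted p-values of 0.1197, 0.0974 and 0.0850 in limma, and CP1 without hda15-1 2, with 0.0514. EXPA1 and OCT1 also lost it without wild type 3 or hda15-1 2, GASA6 without hda15-1 2 or hda15-1 3, and OCT1 without hda15-1 3.

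Rises among the same 12 also included metabolic genes and a non-coding RNA. CYP83B1 (AT4G31500), a cytochrome P450 of indole glucosinolate synthesis, rose from 3.74 ± 2.73 to 50.7 ± 17.8 FPKM (SD, n = 3 each). SOT16 (AT1G74100), a sulfotransferase of glucosinolate synthesis, rose from 4.89 ± 0.432 to 30.6 ± 5.10 FPKM. AT1G28660, of the GDSL esterase family, rose from 1.04 ± 0.779 to 9.63 ± 2.003 FPKM. It lies beside its called relatives AT1G28650 and ARAB-1, both named outside the rule. Reads shared between such copies make each value uncertain. ARAB-1 was listed at 0.355, 0 and 0 FPKM in wild type and at 3.65, 3.75 and 5.67 FPKM in hda15-1. DIN10 (AT5G20250), of the raffinose synthase family, was listed at 0.2995, 0.133 and 0 FPKM in wild type and at 8.19, 4.101 and 3.48 FPKM in hda15-1. The largest log2 fold change was that of the long non-coding RNA AT3G06955, at 4.50 ± 0.52 (SE), listed at 1.57, 0 and 1.92 FPKM in wild type and at 21.0, 72.7 and 52.3 FPKM in hda15-1. Adjusted p-values in limma lay between 3.26e-03 for SOT16 and 0.0213 for DIN10. CYP83B1, AT1G28660, DIN10 and AT3G06955 each lost the call in 4 or 5 of the 6 fits without 1 library, with adjusted p-values of up to 0.105, 0.1197, 0.1197 and 0.104. GASA6, OCT1 and DIN10 overlap an annotated gene on the other strand by 206, 8 and 82 bp at their ends, and whether counting used strand is not given, so only reads in these ends are uncertain.

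All 3 genes that fell are named. Beside HDA15 they were 2 long non-coding RNAs. AT1G07887, on chromosome 1 from 19963067 to 19964105, was at 20.4, 22.3 and 22.9 FPKM in wild type and listed at 0.382, 0 and 0 FPKM in hda15-1 (adjusted p = 1.97e-04, limma). It overlaps HEI10 on the same strand and MRD1 on the opposite strand, so its reads cannot be separated from theirs. AT2G05695, on chromosome 2 from 5009533 to 5009872, fell from 84.0 ± 8.69 to 4.89 ± 3.08 FPKM (SD, n = 3 each), a log2 fold change of -3.96 ± 0.32 (SE; adjusted p = 4.27e-03, limma).

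**Figure D1:**
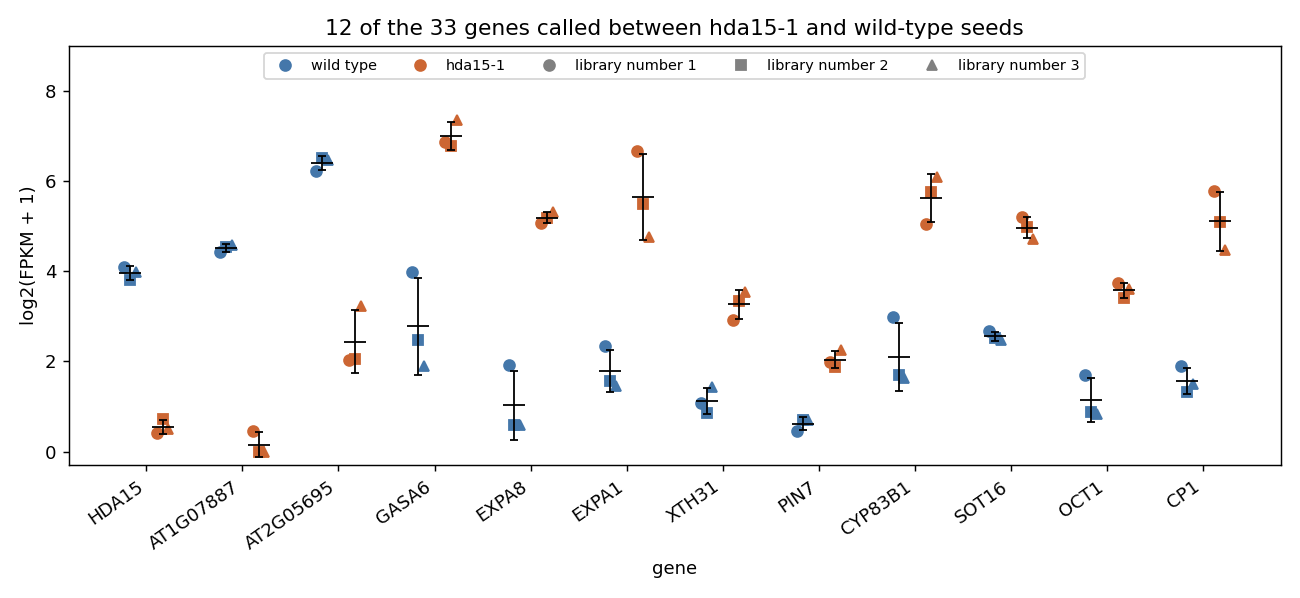
Levels of 12 of the 33 genes past the threshold, as log2(FPKM + 1) on the vertical axis, with 1 point per library, a bar at the mean of 3 libraries and whiskers of 1 SD. Blue points are wild type and orange points hda15-1, and marker shapes give the library number; the 2 groups do not overlap for any gene shown, and HDA15 was at 0.338 to 0.651 FPKM in the hda15-1 libraries.

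For these genes the groups did not overlap, so the sign was bound to hold in both sets of libraries. Only the size of the difference could vary. Among the 4 libraries numbered 2 and 3, the log2 difference between genotypes was 4.66 for EXPA8, 3.62 for EXPA1, 4.89 for GASA6 and 4.26 for CYP83B1. Between the 2 libraries numbered 1 it was 3.16 for EXPA8, 4.34 for EXPA1, 2.90 for GASA6 and 2.06 for CYP83B1. For HDA15 it was -3.28 and -3.68. Wild type 1 had more EXPA8 and GASA6 than the other wild-type libraries, with 2.77 FPKM of EXPA8 against 0.499 and 0.499, and 14.7 FPKM of GASA6 against 4.55 and 2.70.

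The expansin list was higher in hda15-1 in camera, with an adjusted p of 2.68e-16, and in fry, with 0.0356, but did not pass with an estimated correlation, with 0.108. Of 9 expansins tested, 2 rose over all genes tested (EXPA8 and EXPA1) and 7 did not pass, while 8 rose adjusted over the list alone. Their median log2 fold change was 1.76, and 8 of the 9 were above 0. EXPA3 was at 7.23 ± 4.18 FPKM (SD, n = 3) in wild type and 29.2 ± 2.301 FPKM (SD, n = 3) in hda15-1, with an adjusted p of 0.114 over all genes in limma. EXPA2 was at 38.6 ± 34.7 FPKM (SD, n = 3) in wild type and 189.1 ± 50.6 FPKM (SD, n = 3) in hda15-1, with an adjusted p of 0.223 in limma. Both passed without wild type 1, with adjusted p-values of 0.0175 and 8.94e-03 in limma. The mean log2 level of the list was 3.09 in wild type 1, against 2.290 and 2.196 in the other wild-type libraries and 4.25 to 4.72 in hda15-1. The list median was 1.70 among the 4 libraries numbered 2 and 3, and 1.88 between the 2 numbered 1.

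Genes of xyloglucan endotransglucosylases, which cut and rejoin wall xyloglucan, were also higher as a list in camera, with an adjusted p of 8.31e-10, and in fry, with 0.0356. With an estimated correlation the list did not pass, with 0.108. Of 8 tested, 1 rose over all genes (XTH31) and 7 did not pass, while 5 rose adjusted over the list alone. XTH31 (AT3G44990) rose from 1.2002 ± 0.444 to 8.77 ± 2.07 FPKM (SD, n = 3 each), a log2 fold change of 2.15 ± 0.23 (SE; adjusted p = 0.0142, limma). It lost the call in 4 of the 6 fits without 1 library, with an adjusted p of up to 0.0949 without hda15-1 2. XTH9 was at 0.395 ± 0.246 FPKM in wild type and 2.21 ± 0.275 FPKM in hda15-1, and XTH19 at 5.43 ± 3.88 FPKM in wild type and 23.2 ± 3.95 FPKM in hda15-1. XTH22 was at 6.81 ± 0.8999 FPKM in wild type and 10.05 ± 0.678 FPKM in hda15-1.

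The list of gibberellin perception and response was higher in camera, with an adjusted p of 5.21e-04, but not with an estimated correlation (adjusted p = 0.108) or in fry (adjusted p = 0.0620). Of 8 genes tested, GASA6 alone rose, over all genes and adjusted over the list alone. The next genes in order of p were RGL2 and GAI, which code for DELLA proteins that hold back the gibberellin response. RGL2 was at 77.1 ± 6.61 FPKM (SD, n = 3) in wild type and 105.5 ± 3.37 FPKM (SD, n = 3) in hda15-1, and GAI at 210.6 ± 25.4 FPKM in wild type and 304.6 ± 84.3 FPKM in hda15-1. Without hda15-1 1 the list's adjusted p in camera was 0.0798, and among the 4 libraries numbered 2 and 3 it was 0.280.

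None of the 7 gibberellin synthesis genes tested passed the threshold (camera adjusted p = 0.930). Both GA3OX1 and GA3OX2, which make active gibberellin, were below the minimum mean and are named outside the rule, after their values were seen. GA3OX1 (AT1G15550) was at 0.227, 0.178 and 0.0596 FPKM in wild type and 1.95, 1.85 and 0.906 FPKM in hda15-1. GA3OX2 (AT1G80340) was listed at 0 in all 3 wild-type libraries and at 0.640, 0.928 and 0.546 FPKM in hda15-1. With no filter on the mean, their adjusted p-values in limma were 0.152 and 0.0569, neither past the threshold, and the list's adjusted p in camera was 0.0283. Values this low rest on few reads.

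The 2 auxin lists passed camera, each with an adjusted p of 0.0356, but not with an estimated correlation. That adjusted p was 0.448 for the response list and 0.759 for the list of transport genes and response factors. In fry neither list passed, with an adjusted p of 0.349 for each. Both also lost camera in several fits without 1 library. There the adjusted p reached 0.173 for the response list, without hda15-1 3, and 0.696 for the other list, without hda15-1 1. None of the 4 auxin response genes tested passed over all genes or adjusted over the list alone. IAA4, with the smallest p, was at 2.67 ± 0.0828 FPKM (SD, n = 3) in wild type and 4.38 ± 1.45 FPKM (SD, n = 3) in hda15-1. Of 11 transport and response factor genes, 1 rose over all genes and adjusted over the list alone. This was PIN7 (AT1G23080), an auxin efflux carrier gene, which rose from 0.543 ± 0.152 to 3.14 ± 0.572 FPKM (SD, n = 3 each; adjusted p = 0.0435, limma). It lost the call in each of the 6 fits without 1 library, with an adjusted p of up to 0.181 without wild type 2. AUX1 was at 1.08 ± 0.0843 FPKM in wild type and 2.63 ± 1.40 FPKM in hda15-1. Its list's median was 0.04, and was -0.01 with the libraries scaled to the same upper quartile or the same sum. Neither list passed camera among the 4 libraries numbered 2 and 3.

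**Figure D2:**
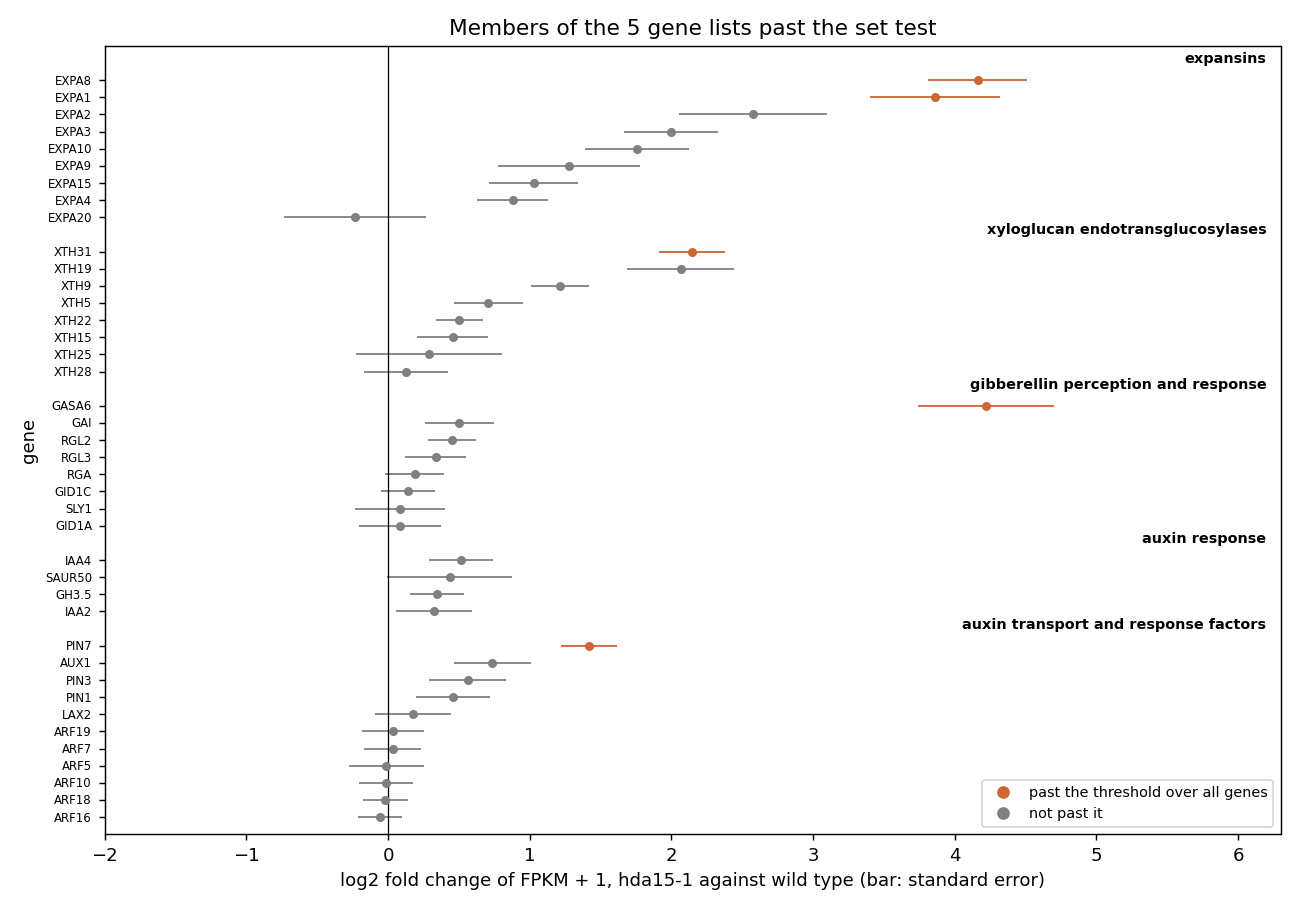
Log2 fold change of FPKM + 1 in hda15-1 against wild type for the tested members of the 5 gene lists past camera, with whiskers of 1 standard error and 3 libraries per genotype. Orange points passed the threshold over all genes tested and grey points did not; the expansins reach 4.16 for EXPA8, and most members of the auxin lists lie near 0.

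The other 17 lists tested did not pass camera, and beside HDA15 none of their tested members passed the gene test over all genes. In alternatives, the cytokinin list passed camera with a mean of at least 5 FPKM (adjusted p = 7.79e-04), and the heat shock list without wild type 1 (adjusted p = 5.03e-03). Of the 19 phytochrome and PIF signalling genes tested, none passed adjusted over the list alone. SPT was at 1.66 ± 0.213 FPKM (SD, n = 3) in wild type and 2.93 ± 0.358 FPKM (SD, n = 3) in hda15-1, with an adjusted p of 0.826 in limma. PIF1, named outside the rule, was at 114.0 ± 10.05 FPKM in wild type and 117.0 ± 31.7 FPKM in hda15-1. Adjusted over the list alone, 1 cytokinin response gene passed. CRF3 was at 3.74 ± 0.736 FPKM in wild type and 8.06 ± 0.463 FPKM in hda15-1 (adjusted p = 0.175 over all genes, limma). The heat shock gene HSP22.0 also passed over its list alone, with lower values, at 34.4 ± 6.90 FPKM in wild type and 12.8 ± 6.25 FPKM in hda15-1 (adjusted p = 0.292 over all genes, limma).

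Genes of seed reserves and dormancy did not pass the test. None of the 14 storage protein and oleosin genes, 14 late embryogenesis and dormancy genes and 18 oil mobilisation genes passed over all genes or adjusted over its list alone. Their adjusted p-values in camera were 0.352, 0.947 and 0.497. SESA4, an albumin gene, was at 1264 ± 82.8 FPKM (SD, n = 3) in wild type and 1909 ± 567.2 FPKM (SD, n = 3) in hda15-1. The cruciferin gene CRC, named outside the rule, was at 17946, 19979 and 0 FPKM in wild type and 17232, 0 and 33132 FPKM in hda15-1, and such zeros can be failed estimates. Without hda15-1 3 the oil list passed camera with an adjusted p of 4.72e-03, and without wild type 3 the storage list passed with 0.0374.

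Lists for abscisic acid did not pass either, with adjusted p-values in camera of 0.901 for 5 synthesis genes and 0.935 for 15 signalling genes. ABI4 was at 7.74 ± 1.21 FPKM (SD, n = 3) in wild type and 12.1 ± 1.82 FPKM (SD, n = 3) in hda15-1, with an adjusted p of 0.834 in limma. CYP707A2, which breaks down abscisic acid, was at 3.74 ± 0.899 FPKM in wild type and 5.82 ± 1.304 FPKM in hda15-1, with an adjusted p of 1.000 in limma. Adjusted p-values in camera were 0.348 for phytochrome and PIF signalling, 0.148 for cytokinin, 0.930 for brassinosteroid and 0.805 for ethylene genes. They were 0.880 for light harvesting and Rubisco, 0.886 for chlorophyll and carotenoid synthesis and 0.705 for the cell cycle. For heat shock, endosperm weakening and the other histone deacetylases they were 0.608, 0.930 and 0.859. The 8 reference genes had an adjusted p of 0.7003. UBQ10, a common control, was at 496.3 ± 64.1 FPKM (SD, n = 3) in wild type and 784.3 ± 235.7 FPKM (SD, n = 3) in hda15-1, with an adjusted p of 1.000 in limma.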

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

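The 33 genes kept the sign of their change in every alternative in which they were tested. Their groups did not overlap, so leaving out libraries or adding a block or batch term could not turn the sign. Of the 33, 9 passed the threshold in each alternative that tested them, 5 of these (HDA15, AT2G05695, SOT16, EXPA8 and PME3) in all 18. The number of higher genes was 30 in the main result and 13 with a mean of at least 5 FPKM, where fewer genes were tested and 18 of the 33 remained in the test. It was 18 with libraries scaled to the same sum, where the cause was not tested, and these numbers also held at 2-fold. With no filter beyond a value above 0, where 21626 genes were tested, 19 were higher by at least 2-fold, and 9 of the 15 genes named for the size of their change passed. With 1 library left out, between 8 and 31 genes were higher and between 3 and 5 lower, at 2-fold as well, between 7 and 14 of the 15 named genes passed, and between 2 and 6 lists passed the set test. HDA15 then lay between -3.50 and -3.34.

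The labels give the replicate numbers no meaning, and across all genes the deviations of libraries of the same number did not correlate positively. The 2 numbered 1 still share some genes. On the axis of the second largest spread across genes, with 24.1% of the variance, wild type 1 lay at -40.8 and hda15-1 1 at -18.4. The other libraries lay at 3.64 to 24.5 there, so these correlations do not exclude a shift shared by the libraries numbered 1. Deviations from the group means of wild-type and hda15-1 libraries of the same number correlated across genes at -0.08, -0.11 and -0.16, and no library correlated best with its own number. With the replicate block, 13 genes were higher, all by at least 2-fold, and 3 lower.

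Chosen after seeing the data, the 4 libraries numbered 2 and 3 gave 73 higher and 12 lower genes, at 2-fold as well, and 2 lists past the set test. The cause was not tested. A batch term for the libraries numbered 1, removal of genes listed at 0 in some libraries and removal of GC content and length trends kept every count within 1.5 times. Camera with an estimated correlation passed 0 lists and fry 2, against 5. The list of auxin transport and response factors turned to lower with a mean of at least 5 FPKM, with an adjusted p of 0.787 and fewer genes tested. Count-based alternatives (other size factors, a count filter, other count tools, recovered reads) were not run, since the tables hold FPKM. Depth limits genes under about 1 FPKM.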

Other observations

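The tests in this part were chosen after the result was seen, except that of the splits. For the GC content and length trend and the batch choices, what would count for or against was written before their own outcome was seen.

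Indole glucosinolates are defence compounds made from tryptophan in this family of plants. Their list of 19 genes includes transporters, and 11 of its genes were tested. Of these, 4 rose in hda15-1 over all genes and 7 did not pass. Adjusted over the list alone, 8 rose and 1 fell. CYP79B2, CYP79B3, MYB51 and CYP81F2, named outside the rule, were below the minimum mean and not tested. The list was drawn up because some of its genes had been called, so a test of the list as a whole says nothing and none is given. Beside CYP83B1 and SOT16, the regulator MYB34 rose from 0.833 ± 0.330 to 5.55 ± 0.643 FPKM (SD, n = 3 each) and the methyltransferase IGMT5 from 2.66 ± 1.02 to 11.8 ± 3.19 FPKM. Both lost the call in fits without 1 library, with adjusted p-values in limma of up to 0.0881 for MYB34, without hda15-1 2, and 0.209 for IGMT5, without wild type 2. The transporter GTR2 was at 3.82 ± 1.08 FPKM in wild type and 10.2 ± 2.43 FPKM in hda15-1, with an adjusted p of 0.185 in limma.

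Of 6 plasma membrane proton pump genes tested, HA2 (AT4G30190), also known as AHA2, rose from 12.6 ± 0.923 to 35.6 ± 4.51 FPKM (SD, n = 3 each; adjusted p = 0.0196, limma). It lost the call in 4 of the 6 fits without 1 library, with an adjusted p of up to 0.157 without wild type 3. These pumps acidify the wall space, where expansins act. HA3 was at 6.89 ± 0.908 FPKM in wild type and 15.8 ± 0.494 FPKM in hda15-1, with an adjusted p of 0.0607 in limma, and HA1, the most abundant, at 405.9 ± 20.4 FPKM in wild type and 420.3 ± 57.6 FPKM in hda15-1. The median log2 fold change of the 6 was -0.01. All these genes were named after their values were seen.

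The expansin rise was weighed against technical trends and a general advance of germination. Removing trends on GC content and exon length left a median log2 fold change of 1.71, with a standard error of 0.34 for the difference in list means, so such a trend is not the whole cause. Among the 4 libraries numbered 2 and 3 it was 1.70, with a standard error of 0.08, so the rise is not limited to the libraries numbered 1. If hda15-1 seeds were further along in germination as a whole, late embryogenesis transcripts would be lower, and their list mean differed by 0.0516, with a 95% interval of -0.79 to 0.90. That interval is too wide to decide, so a later stage of germination as a whole and an effect of HDA15 on these wall genes both remain open. Another variant of the hda15-1 line, or a difference between seed lots, cannot be told apart from an effect of HDA15 either. A single mutant line was used, and the labels do not describe the seed lots. The same holds for the other genes that differed.

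The loss of AT1G07887 in hda15-1 came with lower values of both genes that overlap it, named after their values were seen. HEI10, a gene of meiotic recombination, was at 7.09 ± 0.621 FPKM (SD, n = 3) in wild type and 2.83 ± 0.587 FPKM (SD, n = 3) in hda15-1 (log2 fold change -1.09 ± 0.18 SE; adjusted p = 0.114, limma). MRD1 was listed at 0.881, 1.23 and 0.439 FPKM in wild type and at 0 in all 3 hda15-1 libraries. The 6 tested genes that lie within 15 kb and do not overlap had a median log2 fold change of -0.0769, from -0.34 to 0.12. This argues against a deletion that reaches the tested genes on both sides. At lower positions the nearest genes, MSL4 and U6.9p, both named outside the rule, were at or near 0 FPKM in every library. They were not tested, so a deletion that reaches only them on that side is not covered. A variant of the hda15-1 line at this locus, which could be unrelated to HDA15, cannot be told apart from an effect of HDA15, since a single mutant line was used and its highest library held 0.382 FPKM. Reads shared between the 3 overlapping genes may link their values, and this was not tested.

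The 2 libraries numbered 1 stood apart from the other 4 in some DNA damage response genes in both genotypes. TSO2, a ribonucleotide reductase subunit gene, was at 494.0 FPKM in wild type 1 and 382.9 FPKM in hda15-1 1, against 64.6 to 69.6 FPKM in the other 4, and SMR7, a cell cycle inhibitor gene, at 77.4 and 55.9 FPKM against 6.85 to 8.97 FPKM. Both passed over all genes with genotype in the model, with adjusted p-values of 6.08e-03 and 6.51e-03 in limma, and lay above the median of all genes by 2.69 for TSO2 and 2.95 for SMR7 on the log2 scale. A difference in scaling would move all genes alike, so it is not the cause for these 2 genes. They were picked by that call, so their distance from the median is not a separate test. For the rest of the list scaling stays open. Of the 19 tested members, 8 were picked because they ranked high in these libraries, so a median of the whole list decides nothing. The other 11 lay above the median of all genes by 0.241 ± 0.15 (SE) in wild type and 0.578 ± 0.20 (SE) in hda15-1. These SEs come from the spread over the 11 genes, not over libraries, and genes are not replicates. The median difference of the reference genes was 0.187 in wild type and -0.215 in hda15-1. Tests of the whole list, tried earlier, against the highest reference gene or the median of all genes, were dropped. Taking these 2 libraries as a batch, with genotype in the model, called 7 genes in limma. The highest of the other 8 choices of a wild-type and an hda15-1 library called 4. A shared batch of seed or library preparation would give such a result, but 9 choices are too few for a share under 0.05. Of the 7, 3 were listed at 0 in all 4 other libraries. Without genes listed at 0 the numbers were 5 and 1. No biological explanation was tested, since the labels give nothing that sets the number 1 apart.

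The same 2 libraries differed in 7 other lists in camera with genotype in the model, but with an estimated correlation none of the 7 passed, with adjusted p-values from 0.145 for heat shock to 0.584 for the cell cycle. At the preset correlation, expansins, oil mobilisation, gibberellin synthesis and cell cycle genes were higher in them, with adjusted p-values of 1.50e-04, 1.77e-05, 0.0149 and 9.97e-03, and late embryogenesis, storage protein and heat shock genes were lower, with adjusted p-values of 1.47e-05, 1.56e-04 and 1.62e-06. The cell cycle list has 5 tested genes and includes TSO2, so its rise is not separate from that of the DNA damage response genes. Chloroplast transcripts summed to 1812 FPKM in wild type 1 and 727.6 FPKM in hda15-1 1, against 143.9 to 507.9 FPKM in the other 4. Mitochondrial transcripts did not follow the number, at 1053 FPKM in wild type 1 and 403.6 FPKM, the lowest of the 6, in hda15-1 1.

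With no filter on the mean, 7 genes outside the 33 passed the threshold in limma, 6 higher and 1 lower in hda15-1. They include the sucrose carrier gene SUC1, at 0.166, 0.0896 and 0.0882 FPKM in wild type and 1.39, 1.45 and 1.27 FPKM in hda15-1, and the asparaginase gene ASPGB1, at 0.135, 0.164 and 0.218 FPKM in wild type and 1.98, 1.43 and 1.90 FPKM in hda15-1. Both were named after their values were seen.

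Of the 33 called genes, 4 neighbouring pairs were within 60 kb. The distance was chosen after the positions were seen, so whether this is more than chance gives was not settled. The 3 GDSL esterase genes AT1G28650, AT1G28660 and ARAB-1, which are copies of each other, give 2 of the pairs. XTH31, the peptidase gene scpl48, named outside the rule, and the non-coding RNA AT3G06955 give the others. They lie in a window of 51.5 kb on chromosome 3 that holds 8 tested genes. The other 5 tested genes there had log2 fold changes from -0.24 to 0.13.

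The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split called 33 genes and the highest of the other splits 5, and the same numbers held for genes that differed by at least 2-fold. It was 1 split of the 10 that called as many genes. For the lists past camera the real split gave 5 and the highest other 8, and 3 of the 10 splits gave as many. The split with 8 lists set wild type 1, hda15-1 1 and hda15-1 2 against the rest, which parts the libraries numbered 1 from the wild-type libraries numbered 2 and 3. Among the 4 libraries numbered 2 and 3, 2 lists passed, the expansins and the xyloglucan endotransglucosylases.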
